A study of Saccharopolyspora erythraea with 2 samples.

How the data were processed

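RNA was sequenced from 1 culture each of 2 Saccharopolyspora erythraea strains, N6 and Q7, both sampled at 72 h. Per the labels' protocols, total RNA was extracted from mycelium with Trizol, treated with DNase and depleted of ribosomal RNA. Directional libraries were then made by the dUTP method. Alignment used Bowtie2 2.5.4, per the submitters' processing notes. The counting tool, its strand setting, the reference sequence and any filter on low values are not given in the sources used here. The deposited values are whole-number read counts per gene, with gene lengths, product descriptions and protein-domain names in the same table. Every scaled value was computed from these counts.

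The table held 6330 features. Of these, 6325 carry native locus tags and 5 carry other names (mmfLHPR, antA, gfp, cebR and cymR). For gene names and for which genes neighbour each other, 6321 of the native features were matched by locus tag to the RefSeq gene table of assembly ASM6288v1, and 4 were not matched. Of the 7335 genes in that gene table, 1014 were not analysed here. Because the build behind the counts is not known, no coordinates are given. Names of erythromycin cluster genes came from the table's own Swiss-Prot descriptions or from the reference gene table. The lowest native count was 2 in each library, and the 55 features with 3 counts in N6 had at most 5 in Q7. Genes with few reads and a large ratio therefore seem to have been filtered, at a step not given in the sources used here.

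Counts totalled 3475816 in N6 and 3645029 in Q7. The 7 rRNA and 19 tRNA genes were left out of library sizes and ratios. Effective library sizes were computed by TMM in edgeR 4.0.16 (R 4.3.3) and came to 3947407 for N6 and 3207785 for Q7. CPM values are counts scaled to these effective sizes. Ratios are log2 of Q7 over N6, with a prior count of 0.5 per library scaled to its size. Genes needed at least 50 counts in 1 of the libraries, which kept 4482 of 6299 native genes (71.2%).

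With 1 library per strain, no p-value was computed across genes and no spread between replicates exists. A gene was called higher or lower in Q7 by a fixed rule of size. The ratio had to be at least 2-fold, and its 95% exact counting interval (conditional binomial, Clopper-Pearson) had to lie on one side of 1. Intervals in brackets after a log2 ratio are these counting intervals. CPM carries exact Poisson intervals and shares of counts carry exact binomial intervals. All of them cover counting error only and compare these libraries, not the strains. For a feature at 0 counts in N6, the fold was computed against a floor of 3 counts in that library and is a lower bound.

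The median log2 ratio of a gene list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Random lists drew genes singly, so a list of genes transcribed together can reach an extreme percentile more easily. A list was said to stand apart under percentile 2.5 or over percentile 97.5. Lists with fewer than 5 measured members were given values only. The 37 lists were drawn by words in the product names, by locus range for the erythromycin cluster and by locus tag for 8 regulators. Runs of at least 5 neighbouring genes called in the same direction were set against 1000 shuffles of gene order.

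The rule for which genes to name, the lists, the design and most alternatives were fixed before the data were examined. The rule took the 15 highest and 15 lowest called genes with an informative product name, every gene of the erythromycin cluster and the 8 regulators. It also took the 4 members of each list with the largest absolute log2 ratio, the 5 most abundant genes, and the ends of the 5 longest runs.

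The rule was tested on simulated Poisson counts for Q7 against N6 with 200 changed genes; 4264 genes passed the count minimum. At 2.5-fold, 32 of 32 genes made higher and 32 of 33 made lower (97.0%) were called. At 4-fold, 33 of 33 were called in each direction. At 1.5-fold, 0 of 30 and 0 of 33 were called, as were 0 of 4070 unchanged genes. Of 200 random lists of 20 unchanged genes, 11 (5.5%) fell outside percentiles 2.5 to 97.5. In addition, 1 list shifted by 0.5 on the log2 scale reached percentile 100. The simulated counts held counting error only, with genes drawn independently. They therefore do not show how often genes or lists would differ between 2 cultures of the same strain. The measured log2 ratios had standard deviations of 0.65 to 0.98 across genes within deciles of expression. The percentile of the shifted list therefore does not show that such a shift would be found in these data.

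Alternatives were scaling by library total, DESeq2 1.42.0 size factors and upper quartile. Others were no count minimum or one of 200, a prior count of 2, rRNA and tRNA kept in, the 10 most abundant genes left out of the scaling, calls at 1.5-fold and 4-fold, and random lists matched in 5 bins. Further alternatives were added after seeing the data. The first subtracted a running trend over expression (lowess, fraction 0.3). The second subtracted a uniform background from N6, set at the 5th percentile of its counts per kb. The third drew random lists in 5 bins of expression from genes within a list's own range of lengths, leaving out its shortest and longest 5% of members. Python 3.11.15, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.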

Results

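Saccharopolyspora erythraea is the actinomycete that makes the macrolide antibiotic erythromycin. Gene expression was measured by RNA sequencing in the industrial strain N6 and in Q7, which the labels describe as N6 carrying an artificial control system named hQSCS. Each strain was sampled once, at 72 h of culture, so n = 1 per strain. The labels call the treatment fermentation, while the growth protocol names TSB, a rich broth. The question, from the series title, is how the control system affects the native transcriptome during erythromycin production. Counts totalled 3475816 in N6 and 3645029 in Q7, with a median of 114 and 81 per native gene. No difference below has a replicate check.

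Of the 5 features named outside the native locus tags, 4 were expressed in the Q7 library and all 5 had 0 counts in the N6 library. A count of 0 in N6 allows up to 0.76 CPM. The most abundant was gfp, the gene of green fluorescent protein, with 962 counts in Q7 (299.9 CPM, 281 to 319), at least 394.6-fold higher than in N6. The features cebR (306 counts, 95.4 CPM, 85.0 to 107), antA (168 counts, 52.4 CPM, 44.8 to 60.9) and mmfLHPR (127 counts, 39.6 CPM, 33.0 to 47.1) were at least 125.5-fold, 68.9-fold and 52.1-fold higher. The cymR feature had 2 counts in Q7 (0.62 CPM, 0.08 to 2.25), which is under the floor. Per kilobase, gfp lay at percentile 91.3 of the native genes of the Q7 library, antA at 72.6, cebR at 65.8 and mmfLHPR at 27.2. The 5 features together held 1565 counts in Q7. The counts of gfp, cebR, antA and mmfLHPR go with the labels of the libraries; those of cymR do not show whether Q7 carries it.

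Among 4482 native genes past the count minimum, 266 were higher and 758 lower in the Q7 library, so that 26.0% of the calls were higher. The steepest differences were in the lower direction. SACE_0661, a uracil-xanthine permease family protein, went from 158 counts in N6 to 14 in Q7 (log2 ratio -3.16 [-4.10, -2.41]). The iron uptake permease gene efeU went from 505 to 75 (-2.44 [-2.82, -2.10]). In the other direction, SACE_5145, an ArsI/CadI family heavy metal resistance enzyme, had 16 counts in N6 and 66 in Q7 (2.31 [1.54, 3.23]). SACE_0410, a copy of the nucleoid-structuring protein Lsr2, had 615 and 1423 (1.51 [1.37, 1.65]). The balance of calls depended on the scaling. By library total, which moves the median of all genes by -0.37 relative to TMM, 45 genes were higher and 1144 lower (3.8% higher), and these hold all 758 of the lower genes and no higher gene outside the 266. Only 45 of the 266 higher genes kept their call under that scaling. Genes named below that lost it include SACE_0067 (0.99 by library total), sodN (0.98), groES (0.89), sucC (0.73) and mdh (0.70). The ribosomal protein genes named below lost it too. Short genes had higher ratios: the decile of shortest genes (median 285 bp) had a median of 0.52 and 94 of the higher genes, and the decile of longest genes (median 2317 bp) had -0.16 and 1.

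**Figure D1:**
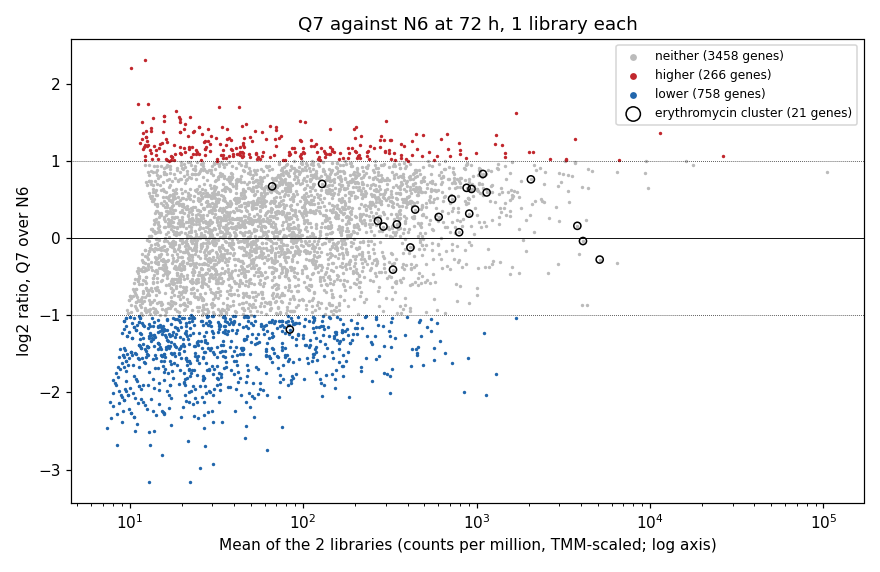
Each point is a native gene past the count minimum; the x axis gives the mean of the N6 and Q7 libraries in TMM-scaled CPM on a log axis, and the y axis the log2 ratio of Q7 over N6. Red points are the 266 higher genes, blue points the 758 lower genes, and open circles the 21 erythromycin cluster genes, of which 1, ermE, lies among the blue points; dotted lines mark a 2-fold difference.

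In the erythromycin biosynthetic cluster, the resistance gene was the only one that differed by 2-fold or more. Of the 21 cluster genes in the table, 0 were higher and 1 was lower. The lower gene was ermE, which encodes the rRNA methyltransferase that protects the producer from its own antibiotic. It had 460 counts in N6 and 164 in Q7 (-1.19 [-1.46, -0.93]). Among the others, 16 had log2 ratios above 0 and 4 below. The cluster median was 0.27 with TMM scaling, at percentile 14.8 of matched random lists, whose own median was 0.47. Matched in 5 bins of expression, the percentile was 26.5. Against random lists limited in length, a comparison chosen after seeing the data, 19 of the genes lay at percentile 53.8 (median of those lists 0.30). The cluster median changed sign to -0.10 by library total. It was -0.09 once a trend with expression, examined after seeing the data, was subtracted. Cluster genes took 2.62% of the counts in N6 (2.60 to 2.64) and 2.29% in Q7 (2.28 to 2.31).

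Within the cluster, the pooled counts of the 3 polyketide synthase genes, which build the macrolactone ring, had a lower ratio than those of the other 18 genes, with overlap between single genes. The ratio was -0.28 [-0.31, -0.25] for eryAI (22191 and 14853 counts), -0.04 for eryAII and 0.16 for eryAIII. Their pooled counts gave -0.08 [-0.10, -0.06], while the other 18 genes pooled gave 0.46 [0.44, 0.48]; by library total every one of these values is lower by 0.37. The highest ratios were those of SACE_0720, an epimerase/dehydratase (0.83 [0.76, 0.90]), and eryG, the methyltransferase of the last biosynthetic step (0.76 [0.71, 0.81]). The beta-glucosidase family gene SACE_0732 had 0.70, the aminotransferase gene eryC1 0.67, the methyltransferase gene SACE_0731 0.65 and the aldo/keto reductase gene SACE_0727 0.64. Of the glycosyltransferase genes, eryBV had 0.59 and eryCIII 0.37. Lower in the range were desII at 0.51, the ring hydroxylase gene eryF at 0.32, SACE_0718 at 0.27, eryK at 0.22, eryCII at 0.18, SACE_0714 at 0.15 and SACE_0717 at 0.07. The aminotransferase gene SACE_0716 had -0.12 and the thioesterase gene SACE_0729 -0.41. None of these 20 genes reached 2-fold.

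**Figure D2:**
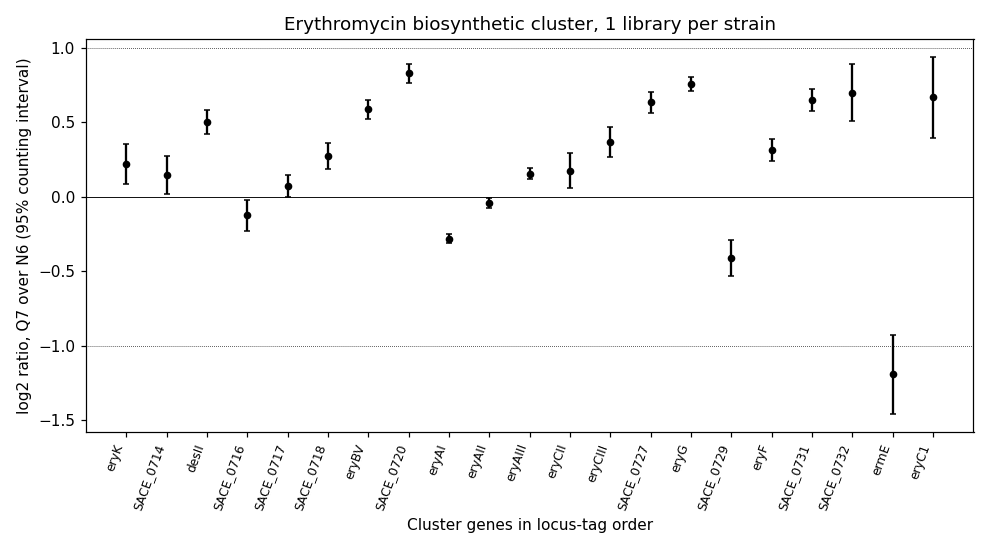
Log2 ratio of Q7 over N6 (y axis) for the 21 erythromycin cluster genes in the table, in locus-tag order along the x axis, with 1 library per strain and TMM scaling. Points are ratios and bars their 95% counting intervals; dotted lines mark a 2-fold difference, and only ermE, at -1.19, lies beyond them.

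None of the 8 regulators fixed beforehand met the rule. The gene of BldD, a developmental regulator, had 259 counts in N6 and 368 in Q7 (0.81 [0.57, 1.04]). The nitrogen regulator gene SACE_7101 had 1294 and 1934 (0.88 [0.78, 0.98]). The TetR family genes SACE_7301 (0.41), SACE_3986 (0.41), SACE_3446 (0.25), SACE_5754 (-0.28) and SACE_7040 (-0.54) had smaller ratios, and SACE_3446 and SACE_5388 (14 and 8 counts) were under the count minimum. The 6 measured regulators had a median of 0.41 at percentile 91.2.

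Of 32 lists with at least 5 measured members, those of ribosomal proteins, the tricarboxylic acid cycle, fatty acid beta-oxidation, oxidative stress and morphology stood apart from matched random lists. All 5 lay above them, and their medians stayed above 0 by library total. Chance would place 1.6 lists apart, on both sides together, if genes varied independently. Genes transcribed together do not, so more lists could stand apart by chance. Of 57 ribosomal protein genes, 4 were higher and 0 lower, with a median of 0.66 (percentile 99.87). Against random lists limited to its range of lengths, a comparison chosen after seeing the data, this list did not stand apart (percentile 91.5). The higher genes were rpmH (1.16), rpsT (1.13), the L25 gene SACE_0811 (1.07) and rpmB (1.02). This list also took in the ribosomal protein modification genes rimO (0.17) and rimI (-0.34). Of 16 genes of the tricarboxylic acid cycle, 2 were higher and 2 lower, with a median of 0.70 (percentile 98.1). Those higher were sucC, of succinate-CoA ligase (1.10 [1.04, 1.16]), and the malate dehydrogenase gene mdh (1.07 [0.97, 1.16]). Those lower were the fumarate hydratase gene SACE_1784 (4272 and 1130 counts, -1.62 [-1.72, -1.52]) and the aconitate hydratase gene SACE_3754 (-1.07 [-1.33, -0.82]). The list also holds leuB of leucine synthesis by its product name.

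Of 45 fatty acid beta-oxidation genes, 4 were higher and 3 lower, with a median of 0.50 (percentile 99.98). Examples are the acyl-CoA dehydrogenase genes SACE_5699 (1.25) and SACE_3580 (1.14), and in the other direction the acyl-CoA synthetase gene SACE_2795 (-1.68) and the acyl-CoA dehydrogenase gene SACE_3993 (-1.11). SACE_2795 entered this list by its product name and lies in the lower run from the hydroxycinnamoyl-CoA hydratase/lyase gene SACE_2794 described below. Its role in beta-oxidation is therefore not established here. Of 24 oxidative stress genes, 1 was higher and 2 were lower, with a median of 0.57 (percentile 99.39). The nickel superoxide dismutase gene sodN had 1504 counts in N6 and 3115 in Q7 (1.35 [1.26, 1.44]), and katG had 0.98 without meeting the rule. The catalase gene SACE_3861 (-1.70) and SACE_1859 (-1.10), which encodes a mycothiol-dependent maleylpyruvate isomerase family enzyme, were lower. Of 11 genes of morphology and sporulation, 2 were higher and 0 lower, with a median of 0.76 (percentile 98.92). Both higher genes encode WhiB family regulators, SACE_6004 (1.56 [1.01, 2.16]) and SACE_6464 (1.18 [0.69, 1.70]). The beta-oxidation and morphology lists no longer stood apart at a count minimum of 200, at percentiles 96.1 and 48.8. With the trend over expression subtracted, the lists of the tricarboxylic acid cycle and of morphology did not stand apart either, at percentiles 94.4 and 91.8.

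Other lists of energy and carbon metabolism lay within the range of random lists matched on expression. Those of cytochrome respiration and glycolysis stood above lists also limited in length (percentiles 99.4 and 99.2). With no count minimum, however, their medians were 0.33 and 0.45, at percentiles 62.0 and 62.6 of lists matched on expression. In cytochrome respiration, ctaC (1.11) and SACE_1684 (1.10) of cytochrome c oxidase were higher and the copper resistance gene SACE_3011 lower (-2.24), among 10 genes with a median of 0.66 (percentile 96.7). Glycolysis had 1 higher gene of 10, gap (1.04), and a median of 0.60 (81.3). The pentose phosphate list had 1 lower gene of 9, gndA (-1.61), and a median of 0.56 (89.4). In ATP synthase, SACE_5295 was lower (-1.52) among 9 genes with a median of 0.48 (44.6). None of the 12 complex I genes was called, with a median of 0.17 (11.7) that changed sign to -0.20 by library total. The suppliers of propionyl and methylmalonyl units, precursors of the macrolactone, had 1 higher gene of 6, the methylmalonyl-CoA epimerase gene mce (115 and 245 counts, 1.39 [1.06, 1.72]). Their median of 0.23 (62.1) changed sign to -0.14 by library total. The 4 measured genes of branched-chain amino acid degradation had a median of 0.72 and no call.

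In transcription and translation, the 4 RNA polymerase core genes had a median of 0.32 (-0.05 by library total) and no call. Of 21 aminoacyl-tRNA synthetase genes, cysS was lower (-1.05), with a median of -0.04 (percentile 8.59). Of 25 sigma factor genes, 3 were lower, SACE_4776 (-1.30), SACE_7154 (-1.12) and SACE_1418 (-1.07), with a median of -0.22 (9.35). Over all genes 758 of 4482 were lower, and regulator families had the following counts. Of 73 two-component system genes, 17 were lower and 0 higher, with a median of -0.28 at percentile 2.93, within the random range, and at 1.47, below it, with no count minimum. They include the sensor kinase gene SACE_4790 (-2.24) and the response regulator gene cseB (-2.13). Of 98 TetR genes, 18 were lower, such as SACE_5812 (1163 and 227 counts, -2.06 [-2.27, -1.85]) and SACE_0384 (-2.28), and 2 were higher, with a median of -0.28 (17.4). Of 7 LuxR genes, SACE_5003 was lower (-1.78), with a median of -0.61 (7.11).

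In stress and uptake lists, groES (1.26) and the Hsp20 gene SACE_2438 (1.12) were among 3 higher chaperone genes of 30. The Clp ATPase gene SACE_6954 (-1.90) and the grpE family gene SACE_7267 (-1.38) were lower, with a median of 0.30 (percentile 60.9). Of 7 cold-shock genes, SACE_5450 (1.44) and SACE_3872 (1.23) were higher and SACE_2658 lower (-1.08), with a median of 0.40 (67.8). The phosphate-binding gene pstS was higher (6900 and 11362 counts, 1.02 [0.98, 1.06]) and the alkaline phosphatase family gene SACE_5775 lower (-1.16) among 17 phosphate genes with a median of 0.48 (88.7, and 99.5 with lengths limited). In iron acquisition, efeU was lower and the Fur family gene SACE_4667 higher (1.30) among 10 genes with a median of 0.20 (75.7). Another Fur family gene of that list, SACE_1498, went the other way without a call (986 and 463 counts, -0.79). SACE_4667 carries the locus number next to katG, SACE_4668, of the oxidative stress list. Nitrogen assimilation had 3 lower genes of 15, the glutamine synthetase family gene SACE_3095 (-1.41), SACE_4093 (-1.21) and ureD1 (-1.09), with a median of 0.12 (51.0). Sugar transporters had 1 lower gene of 9, SACE_5839 (-1.49), with a median of -0.49 (66.4) that turned to 0.10 with the trend over expression subtracted. The 3 measured amino acid and peptide transporter genes had a median of 0.81. With no count minimum, more genes of that list entered and its median was 0.05 (71.1). By library total the chaperone, iron and nitrogen medians changed sign, to -0.07, -0.17 and -0.25.

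In the remaining lists, the methionine adenosyltransferase gene SACE_3900 (1.14 [1.06, 1.22]) and the cystathionine gamma-synthase gene SACE_0902 (1.11) were higher and SACE_6349 lower (-1.01), among 14 sulfur genes with a median of 0.22 (percentile 53.5). The CTP synthase gene pyrG was lower (2814 and 1028 counts, -1.15 [-1.26, -1.05]) among 23 nucleotide synthesis genes with a median of 0.23 (53.2). Of 21 cell division and wall genes, SACE_1761 was higher (1.58) and 3 were lower, among them the FtsI gene SACE_5864 (-1.20), with a median of 0.14 (47.5). Of 32 other secondary metabolism genes, 5 were lower and 1 higher, with a median of -0.05 (47.9); the polyketide synthase gene SACE_4306 had -1.57. With a uniform background subtracted from N6, a setting added after seeing the data, this median turned to 0.50 and stood above random lists (99.4). Of 20 cytochrome P450 genes, 3 were lower, SACE_5461 (-2.52), SACE_0125 (-1.51) and SACE_1158 (-1.29), and SACE_4144 was higher (1.26), with a median of 0.38 (92.1, and 99.02 with lengths limited). Of 50 extracellular hydrolase genes, 5 were higher and 12 lower, with a median of -0.05 (43.6); SACE_1404, a subtilisin-like peptidase, had -1.81. Transposases had 4 lower genes of 12, such as SACE_4108 (-2.31), with a median of 0.07 (63.4). In CRISPR and phage genes, the Shedu defence gene SACE_RS36145 was higher (1.41) among 6 genes with a median of 0.30 (60.0). By library total the medians of the sulfur, nucleotide, wall, transposase and phage lists changed sign, to -0.14, -0.14, -0.22, -0.30 and -0.07. No product name matched the quorum signalling list, and the rRNA and tRNA list was kept for library quality.

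**Figure D3:**
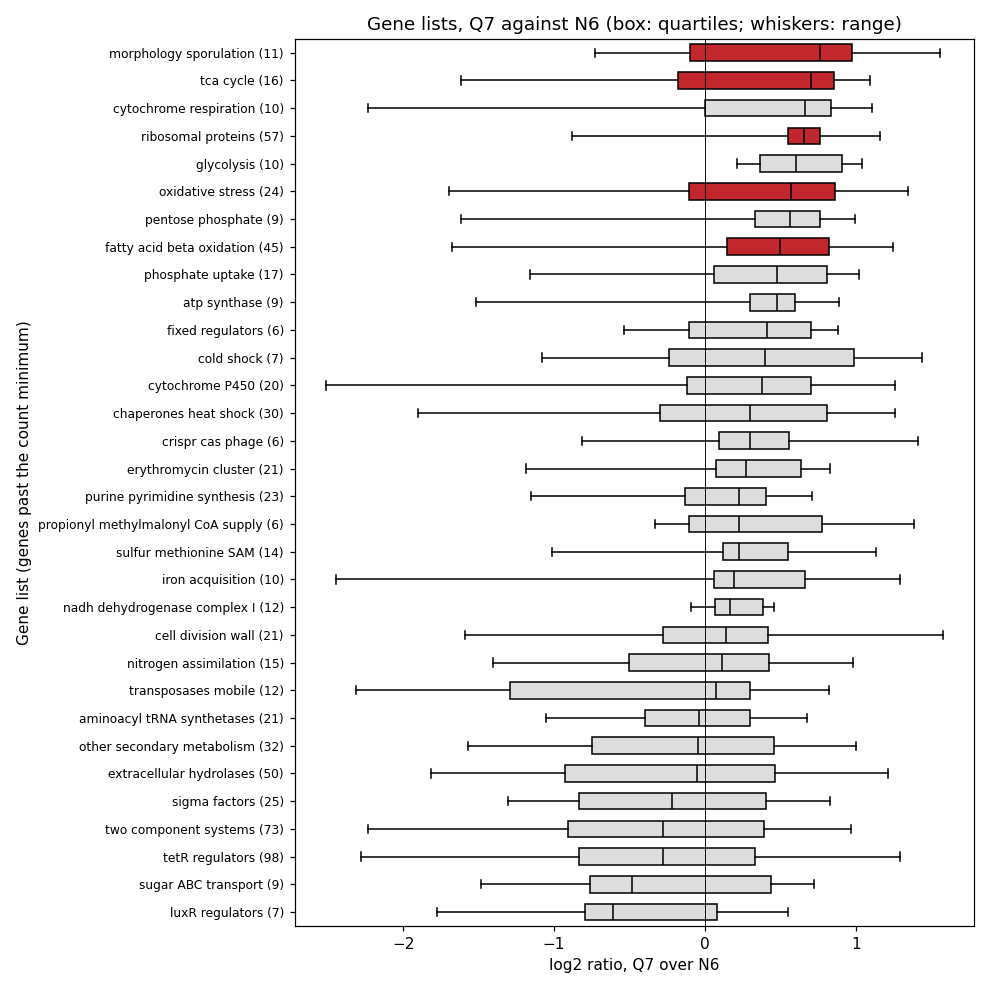
Log2 ratio of Q7 over N6 (x axis, TMM scaling) for the 32 gene lists with at least 5 measured genes (y axis, number of measured genes in brackets). Boxes give quartiles with the median as a line and whiskers the full range; red boxes are the 5 lists that stood above matched random lists, and by library total every value moves by about -0.37, so that medians between 0 and 0.37 change sign.

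Among the 15 highest genes with an informative product name, SACE_5145 was followed by SACE_RS19285, a helix-turn-helix protein (1.73), SACE_1272, another Lsr2 copy (79 and 209 counts, 1.70 [1.32, 2.10]), and the phosphatase gene SACE_3591 (1.65). The ArsR family regulator SACE_4481 (1.57), the iron-sulfur-binding protein SACE_1263 (1.58) and the dihydroxyacetone kinase gene SACE_5291 (1.51) followed. The glucose transporter subunit SACE_2061 had 210 and 485 counts (2.84-fold), the lysozyme gene SACE_7138 had 1.46, cutA had 1.45 and the thiamine-binding protein SACE_6220 had 1.44. Except for SACE_3591, SACE_7138 and SACE_5291 (702 to 1008 bp), these highest genes are short, at 237 to 474 bp. Short genes had higher ratios in general, with a median of 0.52 in the shortest decile, so length was not separated from these differences. The 15 lowest include, after SACE_0661, the membrane protein SACE_3004 (-3.15), the acetyltransferases SACE_0613 (-2.98) and SACE_5272 (-2.67), the cupredoxin SACE_2413 (-2.93) and the GrpB family protein SACE_6699 (-2.81). The polyamine aminopropyltransferase SACE_0456 had -2.69, the major facilitator superfamily (MFS) transporters SACE_5793 and SACE_4121 had -2.59 and -2.46, and the phytoene synthase family protein SACE_6351 had -2.50. The metallo-hydrolase SACE_2751 (-2.46), the GTPase SACE_7050 (-2.43) and the amidohydrolase SACE_4056 (-2.43) also belong to them.

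The most abundant transcripts took a larger share of the Q7 library. The transfer-messenger RNA ssrA, which rescues stalled ribosomes, held 8.51% of counts in N6 and 11.97% in Q7 (0.86 [0.85, 0.87], not called). The RNase P RNA gene rnpB was higher (1.95% and 3.14%; 1.06 [1.04, 1.07]). The hypothetical protein SACE_0067 was higher (25114 and 52415 counts, 1.36 [1.34, 1.38]). The sporulation protein gene SACE_3996 (1.00 [0.98, 1.01], just under 2-fold) and the hydrolase gene SACE_7276 (0.95) were not called. The 10 most abundant features took 17.6% of counts in N6 and 25.2% in Q7. The 7 rRNA genes held 0.0063% and 0.0103% of the counts, and tRNA genes had 987 and 377 counts. Because the counting and filtering steps are not known, these values need not equal the rRNA left in the libraries.

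Runs of at least 5 neighbouring genes with the same call numbered 3, all lower and together 16 genes. Shuffled gene orders gave a median of 0 and at most 2. Shuffling separates neighbours that are transcribed together, so an excess of runs over it is no measure of a strain difference. The longest run held 6 genes from ispD, of isoprenoid precursor synthesis, to cysS. It had 22846 counts in N6 and 5919 in Q7 and a median log2 ratio of -1.71. The gene ispD itself had -1.76 [-1.83, -1.69]. A run of 5 genes from SACE_2794, a hydroxycinnamoyl-CoA hydratase/lyase, to SACE_RS37625 had 1690 and 513 counts (median -1.29). Another 5 genes, from the transposase gene SACE_RS39160 to the cold-shock gene SACE_2658, had 6296 and 2090 (median -1.41). By library total there were 9 runs.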

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

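The alternatives that subtract a running trend over expression or a uniform background from N6, or that limit random lists in length, were chosen after seeing the data; the others were planned. Scaling by library total, which places the median gene at -0.35, gave 45 higher and 1144 lower genes and 9 runs, and turned the erythromycin cluster median to -0.10. A count minimum of 200 gave 145 higher and 338 lower genes, because fewer genes (2486) entered, and 3 lists stood apart. At 1.5-fold, 1038 genes were higher and 1193 lower; at 4-fold, 2 and 92. With no count minimum there were 5 runs. Subtracting the trend gave 5 runs, a cluster median of -0.09 and 3 lists standing apart, without those of the tricarboxylic acid cycle and morphology; subtracting the background gave 5 runs and 6 lists standing apart, with other secondary metabolism added (median 0.50). With no count minimum 7 lists stood apart, with two-component systems below and branched-chain amino acid degradation above the random range added. Limiting random lists to each list's range of lengths gave 8 lists standing apart: ribosomal proteins dropped out (91.5), and cytochrome respiration, glycolysis, cytochrome P450 and phosphate uptake came in. Subtracting the trend also turned the medians of sugar transporters to 0.10, TetR regulators to 0.01, extracellular hydrolases to 0.03, nitrogen assimilation to -0.05, complex I to -0.17 and RNA polymerase to -0.14. The hydrolase median was 0.40 at 200 counts and 0.14 with the background subtracted. The iron median was -0.32 at 200 counts, and that of propionyl and methylmalonyl supply -0.08 with no count minimum. The causes of these shifts were not tested beyond the construction of each setting. Otherwise higher genes ranged from 231 to 376, lower genes from 542 to 974, and the cluster median from 0.24 to 0.29. Of 108 named genes that were called, 85 were still called by library total, 61 at 200 counts, 73 with the trend and 102 with the background subtracted, 107 with DESeq2 size factors and all 108 with a prior count of 2. All 108 kept their direction except SACE_1305, an adenylation domain gene with 85 and 30 counts, which turned to 0.93 when the background was subtracted from N6; its long coding length makes that background large. No paired analysis was possible because each strain had 1 sample. Ratios of deposited normalized values were not run, since only counts were used. At these depths counting error sets a floor: cymR, with 2 counts in Q7, could not be told from 0.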

Other observations

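The families, domain groups and tests of this part were all chosen after the ratios were seen. Of 22 measured genes for DUF397 proteins, a family of small actinomycete proteins, 12 were higher and 1 lower, with a median log2 ratio of 1.04 (0.67 by library total) at percentile 100 of matched random lists. These are very short genes, and against random lists from the 178 genes in their range of lengths, which had a median of 0.44, 18 of them lay at percentile 99.9. Examples are SACE_1545 (113 counts in N6 and 227 in Q7, 1.30 [0.97, 1.64]) and SACE_5304 (148 and 326, 1.44 [1.15, 1.73]), and SACE_RS38605 was the lower gene (-1.60). Of 6 WhiB genes, which are also members of the morphology list, 2 were higher, with a median of 0.95 at percentile 99.94; too few lay in a common range of lengths to draw length-limited lists. Of 3 measured Lsr2 genes, SACE_0410 and SACE_1272 were higher and SACE_1273 had 0.33, or -0.04 by library total. These short genes, of 345 to 444 bp, were too few to place among random lists. Genes were also grouped by the domain names of the table. Of 70 groups with at least 8 measured genes, 6 fell outside percentiles 0.5 to 99.5. If genes varied independently, 0.7 would fall outside by chance. All 6 groups fell outside again after the trend over expression was subtracted. With random lists limited in length, 4 did so; Cupin_2 and Pyridox_oxidase lay at 99.3 and 99.4. Above the range were the Glyoxalase (median 0.88, 5 higher and 2 lower of 15), Cupin_2 (0.81, 8 genes), Aldedh (0.75, 18 genes), Pyridox_oxidase (0.72, 12 genes) and adh_short groups (0.59, 17 genes); these medians stayed above 0 by library total. The Glyoxalase gene SACE_4482 (34 and 72 counts, 1.37 [0.77, 2.02]) carries the locus number next to the higher ArsR regulator SACE_4481. The succinate-semialdehyde dehydrogenase gene SACE_3767 (342 and 592, 1.09 [0.90, 1.29]) belongs to the Aldedh group.

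Among the domain groups, MFS_1 was the only one below percentile 0.5. Copper and heavy-metal proteins had 6 lower and 1 higher of 11 genes, with a median of -1.39 (percentile 0.70). The percentile was 4.66 after the trend was subtracted and 4.84 with lengths limited. SACE_2413 and its neighbour by number SACE_2414, a metal-translocating ATPase (60 and 9 counts, -2.38 [-3.63, -1.42]), were both lower. The iron uptake gene efeU, SACE_2412 (-2.44), carries the number before them, so these neighbours may not vary independently. Within ABC transporters, permease genes had 11 lower and 0 higher of 56 with a median of -0.41 (percentile 7.03). That percentile was 1.11 after the trend was subtracted and 8.54 with lengths limited. The permease domain group BPD_transp_1 (28 genes) lay at 43.5, at 13.1 after the trend was subtracted and at 48.1 with lengths limited. Substrate-binding protein genes had 4 higher and 5 lower of 34 with a median of 0.28 (96.8), which turned to -0.09 by library total, and ATP-binding protein genes had -0.16 (14.7, 52 genes). Of 29 LysR regulators, 12 were lower and 0 higher, with a median of -0.75 (5.73, but 1.62 with lengths limited and 2.66 after the trend was subtracted). The domain group LysR_substrate (25 genes, median -0.79) lay at 4.61, at 5.44 with lengths limited and at 1.88 after the trend was subtracted. GNAT acetyltransferases had 2 higher and 11 lower of 43 genes, with a median of -0.09 (64.6). The neighbour of SACE_0067 by number, the hypothetical protein SACE_0068, had 3289 and 8181 counts (1.61 [1.56, 1.67]). The aconitase gene acnA had 20755 and 9254 (-0.87), while most other genes of the tricarboxylic acid cycle had ratios above 0.

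Weakly expressed genes had lower ratios than abundant ones: the median log2 ratio was -0.77 in the lowest decile of genes by expression and 0.51 in the highest, a gap of 1.28. Reads from genomic DNA in the N6 library would add a uniform background, but subtracting 10.3 counts per kb, the 5th percentile of N6, left a gap of 1.00. Gene length is argued against by Spearman coefficients, across genes, between expression and ratio of at least 0.28 within each quintile of genes by length. Count minimums shape the lowest decile, but the gap between the fifth and the highest decile, both far above them, was still 0.55. A difference between the strains, and GC content, stay open and untested with 1 library each.

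The 59 MFS transporter genes had 31 lower and 0 higher members and a median of -1.08 (-1.44 by library total). Their weak expression does not account for this, since matched random lists had a median of -0.14 and none of 10000 reached the family's. Random lists limited to the family's range of lengths had a median of -0.29 when matched in 20 bins of expression and -0.24 in 5 bins. Examples are SACE_1157 (341 and 55 counts, -2.32 [-2.77, -1.92]) and SACE_0785 (834 and 197, -1.78 [-2.01, -1.56]). A lower level of MFS transcripts in Q7 stays a hypothesis: a difference between the strains was not tested with 1 library each, nor was GC content.

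The polyketide synthase genes of the erythromycin cluster had a median of -0.04, against 0.34 for the other 18 cluster genes. These are very long genes, and 21 genes of at least 5000 bp outside the cluster had a median of -0.24 (bootstrap SE 0.101), below the 0.02 of all genes. The median of all genes includes the shortest genes, at 0.52 in their decile. Length deciles with median lengths of 711 to 1527 bp, nearer to most other cluster genes, had medians from -0.13 to 0.09. The comparison with all genes can therefore overstate how far long genes lay below genes of that length. Those 21 genes were not matched on expression, and ratios rose with expression, so their low median may reflect weak expression. Gene length, or something that goes with it such as RNA integrity, stays a candidate explanation for the difference within the cluster. An effect of the control system on these genes stays open, since no test here separates it from length.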
